A study of Mus musculus with 4 samples.

How the data were processed

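The samples were 4 libraries of genomic DNA from the mouse cell line ATDC5, enriched for 5hmC with a chemical capture kit, per the labels' protocols. The labels put 2 in the chondroprogenitor stage at day 0 and 2 in the chondrocyte stage, at days 19 and 20. Per the file headers, each deposited list held the peaks with a 10-fold enrichment in the merged samples of 1 stage, so replicates were pooled and could not be compared. What the 10-fold was relative to is not given in the sources used here, nor is whether the day 19 library entered the merged day 20 list. FastQC, cutadapt, BWA and MACS 1.4.2 and the genome build GRCm38 (mm10) are named in the submitters' processing notes, with no role or order. The deposited values were start and end positions in base pairs, a gene symbol and a transcript accession. No fold, height or p-value per peak was used, and read depth is not given in the sources used here.

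The day 20 list had 56698 entries, of which 3 had no readable end position and were left out. No list held overlapping or duplicate peaks. The authors gave a gene symbol to 50.1% of day 0 and 60.3% of day 20 peaks, and 98.7% and 99.6% of those matched the gene table by transcript accession or, failing that, by symbol. Of the matched peaks, 84.5% and 89.2% overlapped their own gene and 99.0% and 99.9% lay within 10 kb of it, which fits the build named. In 89 entries the symbol had turned into a calendar date, as spreadsheets do with the septin and MARCH genes, and the transcript accession was used there.

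Gene positions came from the RefSeq genes of GRCm38.p6, with 49976 placed genes, 21896 of them protein-coding. The table gave gene start and end without strand or exons. The planned split into promoter, exon and intron was therefore replaced by position in a protein-coding gene, in another gene, within 5 kb of a gene or farther away, and by distance of at most 1 kb to either end of a protein-coding gene. Strand and exon annotation were not used here.

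Peaks counted as shared when they overlapped by at least 1 bp. Chance overlap and location were measured with 100 random placements of peaks within the span of their own chromosome, without excluding assembly gaps or unmappable sequence. A gene carried a peak when the peak overlapped the gene body by at least 1 bp. For each of 17 fixed gene lists with 431 members, all found in the table (2 by an older symbol), the number of members with a day-20-only peak was set against 10000 random lists of protein-coding genes matched on deciles of gene length. A percentile gives the share of random lists below the observed value, with ties counted in equal parts on both sides. Shares have Wilson 95% intervals. No p-value was computed, since there was 1 list per stage and peaks and genes are not replicates.

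Genes named in the text followed a rule fixed before the data were examined. It took 8 genes in every case (Sox9, Col2a1, Acan, Col10a1, Runx2, Tet1, Tet2 and Tet3). From each list it took up to 3 members with the most day-20-only peaks and up to 2 with the most shared and the most day-0-only peaks. It also took the 10 genes of any type with the most day-20-only and the most day-0-only peaks, ties by gene length. A part of the rule that ranked peaks by fold enrichment could not be applied. Other genes in the text, such as list members without a peak, were chosen after their values were seen. The result on fold enrichment at shared peaks was left out for the same reason.

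The overlap and gene list steps were tested on simulated data. All 300 planted shared peaks were found. In lists drawn from the 21896 protein-coding genes, 25 of 25 planted lists and 0 of 25 unchanged lists passed the 97.5th percentile. Planted lists had peaks added to members without one, and the simulated peaks were placed at random within chromosomes. The check therefore does not cover smaller excesses or the regional structure of the real list. Alternatives covered the overlap rule, merging of peaks within 1 kb, autosomes alone, peak width, gene region, gene set and the matching of random lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.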

Results

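The series examined 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that TET enzymes make, during cartilage differentiation in culture. The cells were ATDC5, a mouse chondrogenic cell line that grows as chondroprogenitors and forms chondrocytes when insulin, transferrin and selenite are added. Genomic DNA carrying 5hmC was captured chemically and sequenced. There were 4 libraries, 2 from chondroprogenitors at day 0 and 2 from chondrocytes, of which 1 was labelled day 19 and 1 day 20. The data used here were 2 peak lists, 1 for each stage, each made from merged libraries. They held positions and gene symbols, with no height, fold enrichment or p-value per peak. No replicate spread could therefore be measured and no comparison below carries a test between stages. Read depth was unknown. Intervals are Wilson 95% intervals and cover counting error only.

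The chondrocyte list was far longer than the chondroprogenitor list. The day 0 list held 1050 peaks covering 181 kb, and the day 20 list held 56695 peaks covering 38.1 Mb, a ratio of 54.0 in peak number. The peaks also differed in shape. Median width was 134 bp at day 0 (quartiles 118 and 168 bp) and 591 bp at day 20 (quartiles 458 and 783.5 bp). Of the day 0 peaks, 77.0% were narrower than the narrowest day 20 peak, which spanned 176 bp. At the 520 day 0 peaks that overlapped a day 20 peak, the day 20 peak was wider in 99.0%, by a median of 4.71 times. The number of peaks in a list therefore cannot be read as an amount of 5hmC.

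**Figure D1:**
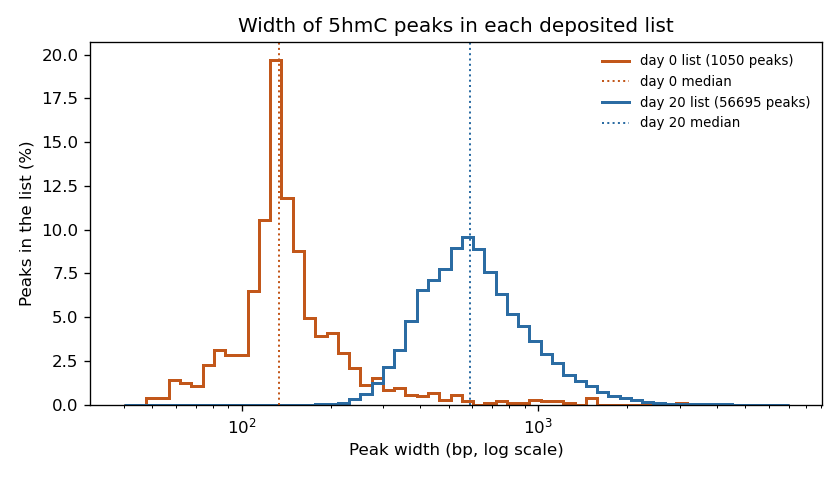
Share of peaks (%) by peak width (bp, log axis) in the day 0 list and the day 20 list, with dotted lines at the medians of 134 and 591 bp. The day 20 distribution starts at 176 bp, above 77.0% of the day 0 peaks.

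The study's design asked how 5hmC differs between progenitors and differentiated chondrocytes, and here the lists were compared by shared and stage-specific positions. Of the 1050 day 0 peaks, 520 overlapped a day 20 peak by at least 1 bp (49.5%, 46.5 to 52.5%). Random placement of the day 20 peaks within their chromosomes gave a mean of 24.6 over 100 placements (range 14 to 36), so the observed overlap was 21.1 times the random mean. The other 530 day 0 peaks had no day 20 counterpart. In the opposite direction, 477 of the 56695 day 20 peaks overlapped a day 0 peak (0.841%, 0.769 to 0.920%), and 56218 (99.2%) were found at day 20 only. What these counts and the gene list results below mean depends on what the 10-fold enrichment required of peaks is relative to, which the sources used here do not state.

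Day 20 peaks lay inside genes more often than randomly placed peaks. Midpoints fell in a protein-coding gene for 54.1% of day 20 peaks (53.7 to 54.5%), against a random mean of 40.7%, and in a gene of any type for 63.6% against 49.0%. Peaks farther than 5 kb from any gene made up 25.3% of the list, against 41.0% at random. Within 1 kb of either end of a protein-coding gene lay 5.09% (4.91 to 5.27%), against 3.14%. The day 0 list stood closer to random placement in protein-coding genes, with 44.0% (41.0 to 47.0%) against a mean of 41.5% and a range of 37.0 to 46.1%. It lay outside the range of all placements for genes of any type, with 55.1% (52.1 to 58.1%) against a mean of 49.7% and a range of 45.8 to 54.0%, and for peaks farther than 5 kb from any gene, with 31.6% (28.9 to 34.5%) against 40.4% and a range of 37.1 to 43.8%. Peaks found at day 0 only fell within 1 kb of a protein-coding gene end in 6.04% (4.31 to 8.40%), and shared day 0 peaks in 3.27% (2.05 to 5.17%). These intervals overlap.

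Peaks were unevenly spread over the chromosomes. Among the nuclear chromosomes, day 20 peaks were densest on chromosome 19, with 35.4 per Mb, and chromosome 11, with 31.4 per Mb. Among the autosomes, chromosome 12 was lowest with 12.2 per Mb. The X chromosome carried 3.45 per Mb against 23.0 per Mb over the autosomes, a ratio of 6.67. At day 0 the X chromosome was also sparse, with 0.0937 against 0.420 per Mb, a ratio of 4.48. The Y chromosome held 1 day 20 peak and no day 0 peak. On the mitochondrial chromosome the order was the opposite: 8 day 0 peaks covered 62.3% of its length and 4 day 20 peaks covered 15.4%.

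At day 20, 8879 of 21896 protein-coding genes (40.6%, 39.9 to 41.2%) carried at least 1 peak in the gene body, and at day 0 386 did (1.76%, 1.60 to 1.95%). Of those 386 genes, 336 (87.0%) also carried a day 20 peak. The count for day 20 depends on list length. Day 20 lists thinned at random to 1050 peaks touched a median of 538.5 protein-coding genes (95% of 100 draws between 511 and 576), against the 386 of the day 0 list. Thinning equalised peak number only. The day 0 peaks were narrower, and 232 of them sat in 35 windows of 100 kb, so the counts are still not on equal terms. Gene length mattered strongly. A day 20 peak was present in 1.69% of genes in the shortest length decile and in 81.9% in the longest. Gene lists were for that reason set against 10000 random lists matched on gene length, and the percentile among them describes these lists and is not a test.

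Of the 17 gene lists fixed before the data were examined, 7 lay above the 97.5th percentile of length-matched random lists by members with a day-20-only peak, with ties counted in equal parts on both sides. These 7 were the lists of cartilage matrix and chondrocyte markers, chondrogenic transcription factors, hypertrophy and mineralisation, TGF-beta and BMP signalling, WNT signalling, insulin and IGF signalling, and proteoglycan synthesis and sulphation. By chance, 0.425 lists would be expected there. By members, no list fell below the 2.5th percentile. In every list, the members with a day 0 peak numbered within the central 95% of day 20 draws thinned to 1050 peaks. For cartilage matrix the day 0 number was 1, against a thinned median of 1 (0 to 3). For WNT it was 0, against 3 (0 to 6). These counts are small, and they do not show a stage difference for any list. By total day-20-only peaks, 5 lists lay above the 97.5th percentile: chondrogenic transcription factors, WNT, insulin and IGF, hedgehog and FGF, and proteoglycan synthesis. Only the first 2 stayed there under every alternative, none of which matched gene length more finely than by decile. The insulin and IGF list fell to percentile 93.39 with random lists also matched on day 0 peaks, 97.415 with flank matching and 95.78 with random genes of any type, and proteoglycan synthesis to 95.11 with matching on day 0 peaks. By total peaks the lists of cartilage matrix (63 peaks against 39.9, percentile 93.55), hypertrophy (45 against 29.2, percentile 89.2) and TGF-beta and BMP (148 against 107, percentile 93.07) did not pass, although the last reached percentile 98.31 by the authors' symbols.

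**Figure D2:**
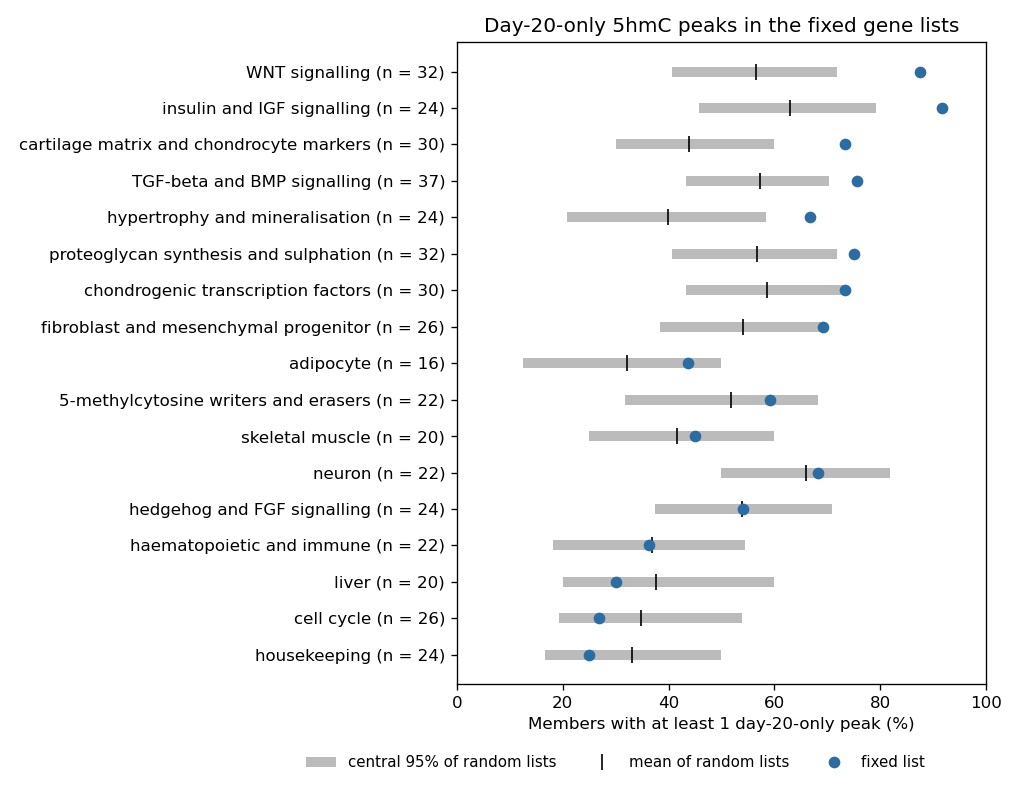
Share of each fixed gene list (%, n measured members) with at least 1 day-20-only peak (points), beside the mean (ticks) and central 95% (bars) of 10000 length-matched random lists. WNT signalling (87.5%), insulin and IGF signalling (91.7%) and cartilage matrix (73.3%) lie above their bars, while the lists of other lineages and of housekeeping genes lie inside theirs.

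Genes of the cartilage matrix carried day-20-only peaks in 22 of 30 members, against 13.2 in random lists (percentile 99.98, ratio 1.67). Col27a1, a fibrillar collagen of cartilage, held 10 peaks, and Col9a1 and Col11a1, which encode chains of the collagen fibrils that also contain type II collagen, held 5 each. Acan, which encodes the large aggregating proteoglycan aggrecan, held 4 peaks in its 61.9 kb on chromosome 7 (79053226 to 79115099, GRCm38), the widest from 79079489 to 79080622. Col2a1, encoding the main collagen of cartilage, held 1 wide peak of 1049 bp on chromosome 15 (97996754 to 97997802). None of these 5 genes had a day 0 peak, but only 1.76% of all protein-coding genes did. In this list only Hapln1, the link protein of aggrecan, had one, at a position not shared with day 20. Members without a day 20 peak in the gene body included Col9a3, Matn1, Cnmd and Fgfr3, although the authors' annotation assigned 1 to Fgfr3.

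Chondrogenic transcription factors carried day-20-only peaks in 22 of 30 members, against 17.6 in random lists (percentile 97.96). The 22 members equal the upper bound of the central 95% of random lists, so this list passed by the rule for ties. It held 260 such peaks in all, against 120 (percentile 99.97). Length was matched by decile only, and the longest decile had a median of 185 kb. Part of this excess can therefore reflect gene length within that decile. Sox5, a partner of Sox9 in cartilage, held 42 peaks across 954 kb, while the authors' own annotation assigned 16 to it. Runx2, which drives chondrocyte hypertrophy and bone formation, held 28 peaks across 319 kb on chromosome 17 (44495987 to 44814797) and no day 0 peak. The widest was 2144 bp long (44504245 to 44506388). Even in the longest length decile only 8.54% of genes had a day 0 peak, so its absence from Runx2 is the usual case. The authors' annotation assigned 19 day 20 peaks to Runx2. Supt3 overlaps Runx2 from 44777118 upwards, where only the peaks starting at 44797259 and 44810299 lie. That overlap therefore cannot account for most of the difference, whose cause was not tested. Nfia held 25. The list fell to percentile 92.6 when random lists were also matched on day 20 peaks in the flanking 500 kb, and to 96.8 on autosomes alone.

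**Figure D3:**
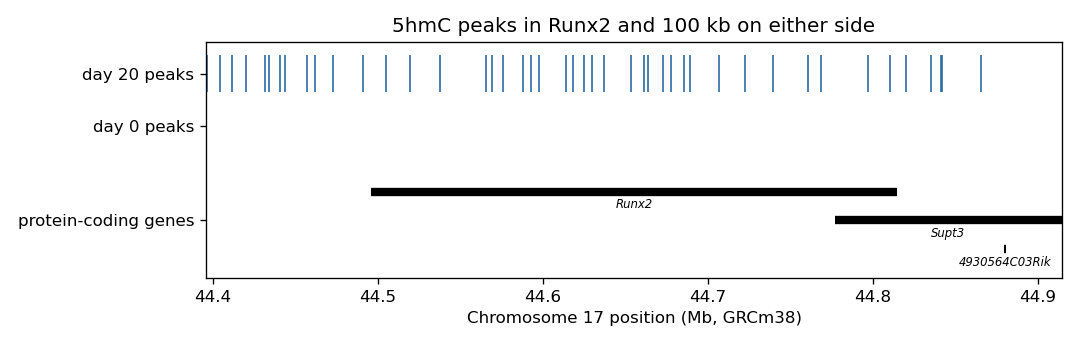
Map of Runx2 with 100 kb on either side on chromosome 17 (x axis, Mb, GRCm38): each line is the midpoint of a peak, and black bars are protein-coding genes. The region held 45 day 20 peaks, 28 of them in Runx2 by position, and no day 0 peak. Over the autosomes the day 0 list held 0.420 peaks per Mb.

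Sox9, the master regulator of chondrogenesis, is a gene of 5.55 kb on chromosome 11 (112782210 to 112787757). It held 1 day 20 peak (112786979 to 112787421) and 1 peak found at day 0 only (112785319 to 112785506). The authors' annotation assigned 3 day 20 peaks to it. The 500 kb on either side held 89 further day 20 peaks, 43 at lower and 46 at higher coordinates, with 3 day 0 peaks in the whole region. That flank count ranked 7 among the 21896 protein-coding genes, whose median was 29. Besides Sox9 the region contained part of 1 other protein-coding gene, Slc39a11.

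**Figure D4:**
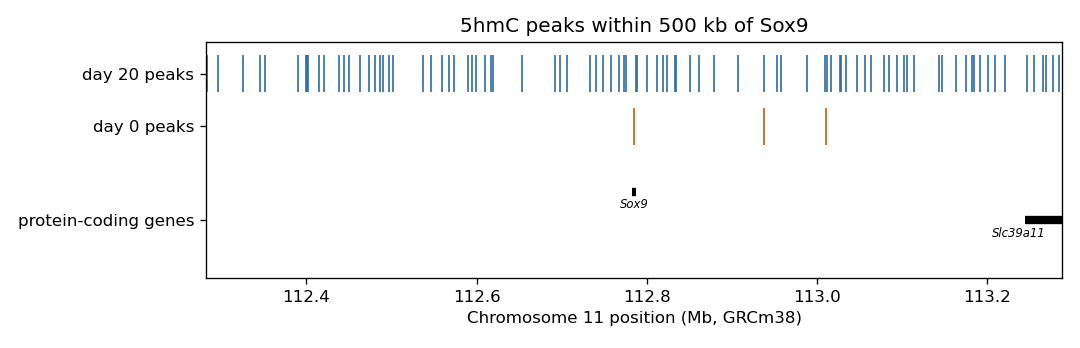
Map of Sox9 with 500 kb on either side on chromosome 11 (x axis, Mb, GRCm38): each line is the midpoint of a peak, and black bars are protein-coding genes. The flanks held 89 day 20 peaks, spread over both sides of the gene, and the whole region held 3 day 0 peaks.

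Hypertrophy and mineralisation genes carried day-20-only peaks in 16 of 24 members, against 9.59 (percentile 99.8). Ank, a transporter in the control of pyrophosphate, held 8 peaks. Alpl, encoding tissue-nonspecific alkaline phosphatase, and Phex, an endopeptidase of phosphate balance on the X chromosome, held 6 each. Col10a1, the collagen of hypertrophic cartilage, held 1 peak that extended past its annotated boundary (34389744 to 34390150 on chromosome 10) and that the authors' annotation did not assign to it. Ihh, Mmp13, Sp7 and Ibsp were among the 8 members without a day 20 peak in the gene body, although the authors' annotation assigned 1 each to Sp7 and Ibsp.

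Signalling lists were covered broadly. WNT genes carried day-20-only peaks in 28 of 32 members, against 18.1 in random lists, and above all 10000 of them. The receptors Ror1 and Ror2 held 25 and 21 peaks and the transcription factor Tcf7l2 held 18. Insulin and IGF genes carried them in 22 of 24 members, against 15.1 (percentile 99.99), with Igf2 and Igfbp6 as the exceptions. Igf1r, the receptor for IGF-1, held 20 peaks, of which 2 were shared with day 0, and Mtor held 7, of which 2 were shared. Igf2r held 12 by position and 7 by the authors' annotation. TGF-beta and BMP genes carried day-20-only peaks in 28 of 37 members, against 21.2 (percentile 99.8), with 30 day 20 peaks in Ltbp1, 15 in Bmp6 and 13 in Smad3. The hedgehog and FGF list did not stand apart by members, with 13 of 24 against 12.9 (percentile 51.1), and by total peaks, with 56 against 36.3 (percentile 97.87), it lost its place with random genes of any type (56 against 53.4, percentile 61.535) and on autosomes alone (percentile 97.185). Boc held 10 peaks.

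Genes of proteoglycan synthesis and sulphation carried day-20-only peaks in 24 of 32 members, against 18.2 (percentile 99.2). Xylt1, which starts the glycosaminoglycan chain, held 22 peaks. Ext1 held 18, of which 1 was shared, and the chondroitin sulphotransferase gene Chst11 held 17, together with 2 peaks found at day 0 only.

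By members, with gene bodies as annotated, the remaining lists lay within the random range. Fibroblast and mesenchymal progenitor genes reached 18 of 26 members against 14.1 (percentile 96.1), with 20 peaks in Tcf4 and 11 in Col5a1. With 5 kb added on both sides of each gene body this list rose to 22 of 26 against 16.1 (percentile 99.565). Among lists of other lineages, adipocyte genes had 7 of 16 members (percentile 86.4), skeletal muscle genes 9 of 20 (percentile 64.4), neuronal genes 15 of 22 (percentile 59.1), haematopoietic and immune genes 8 of 22 (percentile 48.0) and liver genes 6 of 20 (percentile 22.8). Neuronal genes held fewer peaks in total than their length would give, 35 against 90.8 (percentile 0.39), but lay within the random range with flank matching (35 against 65.6, percentile 3.86) and with random genes of any type (percentile 2.73). Cell cycle genes had 7 of 26 members against 9.06 (percentile 18.7), but 15 of 26 against 12.6 (percentile 83.3) with 5 kb on both sides and 12 of 26 against 10.3 (percentile 75.3) by the authors' symbols, so the direction depends on how peaks are assigned. Housekeeping genes had 6 of 24 (percentile 18.5).

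Genes that write or erase 5-methylcytosine carried day-20-only peaks in 13 of 22 members, against 11.4 (percentile 76.9). With 5 kb added on both sides of each gene body the list reached 19 of 22, against 13.3 (percentile 99.65), so its place depends on the gene boundary. Of the TET dioxygenases, which make 5hmC, Tet3 held 8 peaks, Tet1 held 7 and Tet2 held 2. Tet1 also held 2 peaks found at day 0 only on chromosome 10 (62833265 to 62833593 and 62833786 to 62834049), beside a day 20 peak that ended at 62833255.

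Peaks shared between stages and peaks found at day 0 only were too few in the fixed lists to set most of them apart. The insulin and IGF list had shared day 20 peaks in 2 members, against 0.412 in random lists (percentile 96.62, within the random range), and held 4 such peaks, against 0.453 (percentile 99.4). Over all day 0 peaks, this list had 3 of 24 members with a peak, against 0.726 (percentile 98.025). It held 5 such peaks, against 0.934 (percentile 98.595). The 3 members equal the upper bound of the random range, so by members the list passed by the rule for ties. To 1 of them, Igf2r, the authors' annotation assigned no day 0 peak. The 5-methylcytosine list held 2 peaks found at day 0 only, both in Tet1, against 0.290 (percentile 97.575), but had them in 1 member against 0.206 (percentile 89.75). Sox9 and Runx1 were the 2 chondrogenic transcription factors with a peak found at day 0 only.

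The genes with the most day-20-only peaks were long. Wwox held 61, Auts2 59, Foxp1 57, Lrmda 50, and Cacna2d3 and Zfhx3 49 each, with 48 in Pde4d, 45 in Glis3, 44 in Kcnma1 and 43 in Ppargc1a. For Zfhx3 and Ppargc1a the authors' annotation assigned 22 and 6 day 20 peaks, against 51 and 44 by position. The genes with the most peaks found at day 0 only were of another kind. Sfi1 on chromosome 11 held 15, and Pisd-ps1 beside it held 4. On chromosome 1, the immune nuclear body genes Sp140 and Sp110, which overlap each other, held 8 and 7. Gm38510 held 5, C130026I21Rik and A530032D15Rik held 4 each and Gm7592 held 3. C130026I21Rik lies within Gm38510, so its peaks count for both genes. The list ended with 2700054A10Rik and Gm2420, with 3 each. All of these genes lay at least in part in 100 kb windows that held 3 or more day 0 peaks. This nearly follows from their choice, since each gene held 3 or more such peaks itself. Sp140, Sp110, A530032D15Rik, Gm7592 and 2700054A10Rik had no day 20 peak.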

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

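Alternatives without clustered windows, with locally moved peaks, with the authors' symbols, with thinning, with flank-matched or any-type random lists, and those on protein-coding genes or 5 kb margins for location, on merging for the X chromosome and on autosomes for gene lists were chosen after seeing the data. The ratio of peak numbers ranged from 54.7 to 69.2, within 1.5 times the reported 54.0. The share of day 0 peaks shared moved to 56.5% when peaks within 1 kb counted as shared and to 54.3% without the 100 kb windows holding 3 or more day 0 peaks. For day 20 peaks these were 0.991% and 0.761%. Against day 20 peaks moved by 20 to 100 kb, shared day 0 peaks were 14.3 times the mean, in place of 21.1. By construction, the share in genes moved to 64.7% of day 20 peaks with any overlap, to 44.0% and 54.1% of day 0 and day 20 peaks in protein-coding genes, and to 68.4% and 74.7% with 5 kb margins. Genes with a day 20 peak numbered 8879 when protein-coding and 688 after thinning to 1050 peaks, in place of 13585. The number of gene lists above the 97.5th percentile was 7 and ranged from 6 to 9, with the fibroblast and the 5-methylcytosine lists added by 5 kb on both sides of gene bodies. The 7 lists stayed there, except chondrogenic transcription factors with flank matching and on autosomes. By total peaks, the number above was 5, with 6 for 5 kb on both sides, 3 for matching on day 0 peaks, 4 for flank matching, 3 for genes of any type, 4 on autosomes and 7 by the authors' symbols. The cartilage ratio by members stayed between 1.41 and 1.70. No list above that percentile changed direction. Among the others, the cell cycle ratio turned from 0.772 to 1.19 with 5 kb on both sides and 1.16 by the authors' symbols, and the haematopoietic (0.869 to 1.22), hedgehog and FGF (0.959 to 1.27) and neuron lists also crossed 1. Of 82 named genes, 14 changed by over 1.5 times, mostly under the authors' symbols; the cause was not tested. Wilson intervals of 16 to 37 members are wide, so agreement of list ratios within them is a weak check.

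Not run were all thresholds on fold, p-value or FDR, list lengths set by them, promoter regions and fold at shared peaks, since these values or strand were not used here. No paired analysis was possible because the results come from pooled lists and no test, and leaving out a replicate was not possible. Unknown depth limits every count of peaks.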

Other observations

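The tests, their bounds and the gene families here were chosen after the results they measure were seen, and the genes named here that the report does not name were chosen after their values were seen. The block of mineralised-tissue matrix genes on chromosome 5, from Dspp to Spp1 (104170703 to 104441053), held 31 day 20 peaks in 270 kb. The gene bodies held few of them, with 2 in Dmp1, 2 in Mepe, 1 in Spp1 and none in Dspp or Ibsp. No day 0 peak lay in the block, but the day 0 list held only 0.420 peaks per Mb over the autosomes. The 500 kb window around this block held 50 day 20 peaks and ranked 5 of 3717 windows with a peak, whose median was 14. A window beside Sox9 with no protein-coding gene (chromosome 11, 112000001 to 112500000) held 47 and ranked 13. The top window, with 56 peaks, lay on chromosome 10 (84000001 to 84500000) over Nuak1.

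Among gene families taken by symbol, collagens carried a day 20 peak in 40 of 44 genes, against 30.7 in length-matched random lists, but did not stand apart by total peaks (229 against 201, percentile 76.62). Phosphodiesterases carried one in 23 of 25, against 17.1. Olfactory receptors carried one in 6 of 1110 genes, against 46.7, vomeronasal receptors in 0 of 353, against 65.5, and cytochromes P450 in 16 of 92, against 38.9. Clustered protocadherins reached 22 of 57, against 29.6. Fox genes were near random by members, 15 of 44 against 13.8, but held 116 peaks against 47.4, of which Foxp1 alone held 59. Long genes fell apart in the same way. Of 215 autosomal protein-coding genes of at least 500 kb, 67 (31.2%) had no day 20 peak and 53 had at least 20. The longest without one were Ptprd (2271 kb), Lrp1b (2058 kb), Csmd1 (1643 kb) and Dpp10 (1514 kb).

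The day 20 list had 54.0 times as many peaks as the day 0 list. Of the day 0 peaks, 77.0% were narrower than the narrowest of the 56695 day 20 peaks. That value was known before its bound was set, so it does not decide whether the lists differ in fragment length or peak-calling settings. A gain of 5hmC with differentiation, the explanation the design names, cannot be told apart from a difference in depth or calling, because each stage has 1 pooled list.

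About as many day 0 peaks lay outside the day 20 list as inside it. Part of the day 0 list sat in dense clusters: 35 windows of 100 kb with 3 or more day 0 peaks held 232 peaks (22.1%), against a mean of 9.54 peaks under random placement, among them windows at chromosome starts and at Rn45s, the ribosomal RNA gene. These clusters are not the whole cause, since outside the windows the shared portion was still only 54.3% (50.9 to 57.7%). The windows were not chosen by copy number or mappability, which were not tested. Nor were the remaining 374 day-0-only peaks placed without regard to the day 20 peaks: their median distance to one was 10.7 kb, just under all 100 local shifts by 20 to 100 kb (11.4 to 18.3 kb), a narrow margin. Placement anywhere on the chromosome, tried first, gave a median of 33.8 kb. A candidate explanation left open is 5hmC present at day 0 that narrowly missed the day 20 threshold, which these lists do not test.

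Of the 17 fixed lists, 7 lists of cartilage and signalling genes carried day-20-only peaks in more members than most random lists of like length, while the hedgehog and FGF list did not (percentile 51.1). Regional peak density, matched in 5 classes of peak count in the flanking 500 kb, does not account for all of the member counts. After that matching, 6 of the 7 lists stayed above the 97.5th percentile. Density within a class or at a finer scale, and gene length within a decile, were not matched and stay open. By total peaks, chondrogenic transcription factors, WNT and proteoglycan synthesis passed under this matching. Cartilage matrix (percentile 97.025), hypertrophy (91.445), TGF-beta and BMP (88.585) and insulin and IGF (97.415) did not. Expression in every cell type stays open. The housekeeping list lay at the 18.5th percentile, and at most at the 47.06th under the alternatives, but the cell cycle list moved from the 18.7th to the 83.3rd with 5 kb on both sides of gene bodies. The lineage of the cells stays open as well. Above the 97.5th percentile lay 0 of the 5 lists of other lineages, but the adipocyte list, with only 16 members, had a ratio of 1.36, above the 1.25 of the chondrogenic transcription factors. No expression data were analysed here. CpG density was not tested, and whether the pattern arose with differentiation was not settled. At day 0 the insulin and IGF list had 3 of 24 members with a peak, against 0.726 (percentile 98.025). Those 3 members equal the upper bound of the random range, so the list passed by the rule for ties. To 1 of them, Igf2r, the authors' annotation assigned no day 0 peak. The other lists among the 7 lay within the random range at day 0. WNT had 0 of 32 members, against 1.03, and proteoglycan synthesis 2 of 32, against 1.02. These counts are too small to settle whether the pattern was present at day 0.

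At Myc on chromosome 15, the day 0 list held a 923 bp peak (61987425 to 61988347) absent from the day 20 list and a second peak (61989264 to 61989986) with the same end as the day 20 peak (61989088 to 61989986). In 100 kb or longer genes, day 20 peaks were densest in Xxylt1, with 18 in 126 kb, and Wnt5b, with 16 in 112 kb.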
